A study of Mus musculus with 12 samples.

How the data were processed

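Per the labels, mpkCCD cells (clone 11) were grown in medium with 2% dialyzed serum and harvested 24 h after serum removal, with 0.1 nM dDAVP or vehicle present. Chromatin was cross-linked with 1.11% formaldehyde and sheared to about 300 bp, and fragments of 200 to 400 bp were sequenced as 50-bp reads, per the labels' protocols. Reads were mapped to mm10 with BWA, per the labels, and SAMtools and bedtools are named in the submitters' processing notes, with no versions. The deposited count of each interval is the number of reads overlapping a RefSeq transcript from start to end, introns included, per the file headers, so a read is counted in each interval it overlaps and no strand is used. The deposited fraction of each interval's bases with at least 1 read was also given, per the file headers. The removal of duplicate reads and a mapping quality filter are not given in the sources used here. No normalization was applied to the deposited counts.

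Only the 6 IgG libraries were used, and the 6 Pol II libraries were not analysed here. Of 33063 intervals in 5 libraries, 1 was missing in vehicle experiment 2 and was left out. Symbols for 32763 of the 33062 common intervals (99.1%) came from a RefSeq gene table and the GENCODE vM21 annotation of the GRCm38.p6 reference, which has the chromosome coordinates of mm10. GC content was read from that reference for 32980 intervals, and 82 intervals on scaffolds have none. Overlapping and antisense genes share reads.

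Libraries were compared in pairs across genes with at least 40 reads by chi-square. A ratio of chi-square to degrees of freedom under 1.1 was taken as agreement within sampling noise, a limit set after seeing the data. Experiments 1 and 2 of each group met it, so their counts were summed, and their densities averaged, as 1 sample. The design fixed before the data were examined had 6 separate libraries. Summing was decided after seeing the data, so that design is reported as an alternative. The gene lists, the tests, the rule for named genes and most alternatives were likewise chosen before the data were examined. Other alternatives were chosen after seeing the data: the GC model, leaving out experiments 1 and 2 of a group together, and experiments 1 and 2 alone.

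The comparison per interval used edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr and the two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05 over 30912 intervals and no covariate. Standard errors and 95% intervals of log2 ratios came from that fit with its 2 groups of 2. DESeq2 1.42.0 was the other tool. Gene lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, on 1 interval per gene, the longest, for 22433 genes. All 10 lists were adjusted together, and camera with an estimated correlation and fry were alternatives. Of the list members, 28 of 28 vasopressin, 33 of 33 principal cell, 18 of 18 intercalated cell, 21 of 21 other nephron, 31 of 31 immediate early, 48 of 48 housekeeping, 78 of 78 ribosomal protein, 48 of 50 RNA polymerase II, 52 of 52 other organ and 18 of 22 noncoding RNA genes matched an interval.

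Density was computed as RPKM, reads per kb scaled to the reads over 1 interval per gene, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Each list's median was set against 10000 random lists drawn from the same 10 length deciles, and a list was counted when it lay outside their central 95% in each library. This describes the libraries and gives no p-value. A chromosome was counted when it lay at least 20% from the median autosome in each library. With 2 samples per group the smallest two-sided exact permutation p is 0.333. The ratio of promoter-proximal to gene-body density was not computed, since the intervals do not separate the parts.

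The GC model gave each library a weight for each of 12 GC classes of 300-bp tiles, fitted by non-negative least squares on genes of at least 2 kb. Density over the GC model is density divided by the model's value. The weight for tiles of 65% GC or more was 0 in every library but dDAVP experiment 3, where it was 1.36. In that library the weight for tiles of 30 to 34% GC was 0. Values over the model and log2 ratios with the GC offset are therefore less certain for genes of extreme GC content. On simulated data for dDAVP experiment 3 over 20273 genes, the model's weights correlated with the true ones at 0.989 and chromosome levels were off by at most 2.52%. The simulated counts were drawn from the GC model itself, so this does not test whether the model suits the real library. After the model the real library kept a slope of log2 density of 0.175 per 10 GC points. The edgeR step was tested on simulated data with 200 changed intervals among 30912. It recovered 0 of 67 intervals changed 2-fold, 21 of 67 changed 4-fold and 58 of 66 changed 8-fold, with 4 false calls. Without dDAVP experiment 3 it recovered 61.2%, 97.0% and 100%. With 6 separate libraries it recovered 23.9%, 91.0% and 100%. In each simulation the changed intervals were drawn from those with enough expected reads. Counts were drawn independently per interval, without a GC bias in any library. Camera on simulated data over 22433 genes gave 3.71e-102 as p for a list shifted 4-fold and 0.479 for an unshifted list. Both lists were drawn from genes with more reads, and genes were simulated independently. False calls of lists under correlation between genes were therefore not tested by it.

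Named genes followed a fixed rule: each interval called, up to 15 in each direction. With fewer than 20 called, the 5 smallest unadjusted p-values in each direction were added, of which 1 gene is not reported here. The rule also takes 10 fixed genes (Aqp2, Aqp3, Avpr2, Scnn1a, Scnn1b, Scnn1g, Fos, Egr1, Actb and Gapdh), the 10 named genes of at least 1 kb with the highest mean density, and for each list the 2 densest members and the lowest member passing the count filter. The alternatives tried were other size factors, total counts, other count filters, DESeq2, a replicate block with and without a loess offset, 1 interval per gene, autosomes only, each library left out, other summaries of lists and chromosomes, and those added later. Total counts per library were 10588927 to 19748658, and a gene with few reads has a wide interval. Plots were drawn with matplotlib 3.10.9.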

Results

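Chromatin of mpkCCD cells, a mouse cell line of renal collecting duct principal cells, was immunoprecipitated from cells kept with 0.1 nM dDAVP or with its vehicle. dDAVP is a vasopressin analog that acts on the V2 receptor, and the study asked how vasopressin regulates transcription in these cells. The design held 12 samples in 4 groups of 3, with an antibody against Polr2a, the large subunit of RNA polymerase II, or with IgG as the background control. The 6 IgG samples are described here, and the 6 Pol II samples were not analysed here. Reads were counted by the authors over the genomic interval of each RefSeq transcript, introns included, on mouse build mm10. The 6 libraries shared 33062 intervals, which matched 23870 named genes. Total counts over all intervals were 13403860, 12771289 and 12632322 in dDAVP experiments 1, 2 and 3. They were 11185306, 10588927 and 19748658 in vehicle experiments 1, 2 and 3. The median interval held 92 to 155 reads. Read density is given as RPKM, with reads counted over 1 interval per gene as the library size.

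GC-rich genes took a far larger share of the reads in dDAVP experiment 3 than in any other library. Median density in the highest GC decile over that in the lowest was 8.34 in that library. It was 0.837 and 0.841 in dDAVP experiments 1 and 2, and 0.711, 0.714 and 0.473 in vehicle experiments 1, 2 and 3. The share of reads estimated to be distinct, from the bases covered, was 49.01% in dDAVP experiment 3, 70.6% and 71.8% in vehicle experiments 1 and 2, and at least 92.4% in the other 3 libraries. Counts of experiments 1 and 2 differed across genes by about the sampling noise in either group. Chi-square over its degrees of freedom was 1.02 for the dDAVP pair (chi-square p = 0.0400) and 1.01 for the vehicle pair (chi-square p = 0.143). Other pairs within a group gave 5.04 to 89.5. Experiments 1 and 2 of each group were therefore counted as 1 sample, which leaves n = 2 per group. Between the groups, dDAVP experiments 1 and 2 against vehicle experiments 1 and 2 gave ratios of 1.69 to 1.78. These are below vehicle experiments 1 and 2 against vehicle experiment 3 (5.04 and 5.13). Experiments 1 and 2 thus lay closer across treatments than to experiment 3 of their own treatment. dDAVP experiment 3 against vehicle experiment 3 gave 148.6. The sources used here do not say that the experiments were separate cultures, so p-values measure only the spread between these samples, which may be technical. The estimate of distinct reads assumes an even spread of reads along each interval, so crowding on GC-rich parts would lower it too. By that estimate the counts may hold copies of the same molecule, so they cannot be taken as counts of independent molecules.

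**Figure D1:**
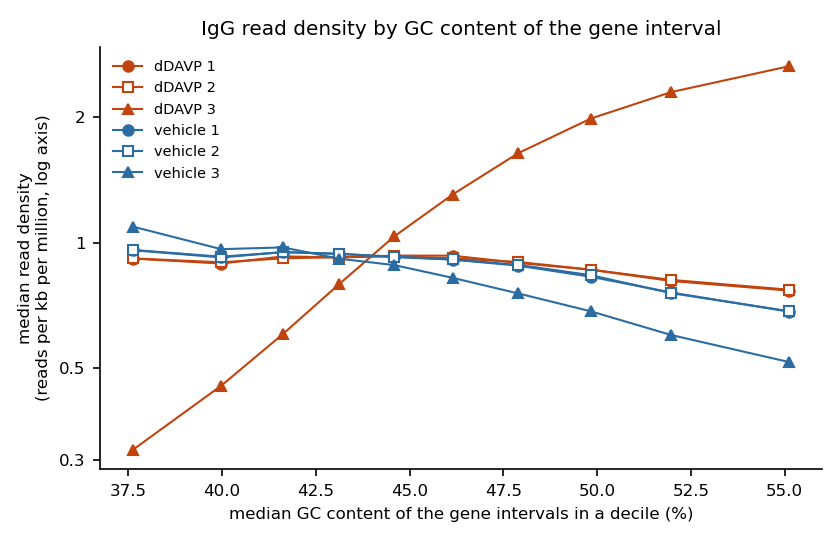
Median read density of gene intervals (RPKM, log axis) against the median GC content of their decile (%), with a line for each of the 6 IgG libraries. dDAVP experiment 3 runs from 0.318 in the lowest decile to 2.65 in the highest, while vehicle experiment 3 runs from 1.09 to 0.517.

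The comparison of dDAVP with vehicle per interval asked whether the background under the Pol II signal differs with treatment. No gene of vasopressin-regulated water or sodium transport passed the test. Over Aqp2, the vasopressin-regulated apical water channel, density was 1.76 ± 1.48 (SD, n = 2) with dDAVP and 0.584 ± 0.014 (SD, n = 2) with vehicle. Vehicle experiments 1, 2 and 3 had 0.717, 0.470 and 0.574. Since experiments 1 and 2 were averaged first, an SD can be smaller than the spread over the libraries. The log2 ratio of dDAVP to vehicle for Aqp2 was 1.25 ± 0.67 (SE) with a 95% interval of −0.41 to 2.92 (edgeR adjusted p = 0.619). Aqp2 spans 99579056 to 99584545 on chromosome 15 and held 196 reads over the 3 dDAVP libraries and 88 over the 3 vehicle libraries. Aqp3, the basolateral water channel, had a log2 ratio of 1.33 ± 0.68 (SE). Scnn1a, Scnn1b and Scnn1g, the subunits of the epithelial sodium channel, had 0.99, 0.56 and −0.06. Avpr2, the V2 receptor gene, held 1 to 18 reads per library and was below the count filter. Fos and Egr1, transcription factors of the immediate early response, had 1.56 and 0.75. The cytoskeletal gene Actb and the glycolytic gene Gapdh had 1.40 and 0.81. Adjusted p in edgeR's test was 0.619 for these genes except Scnn1g (0.920) and Egr1 (0.671).

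**Figure D2:**
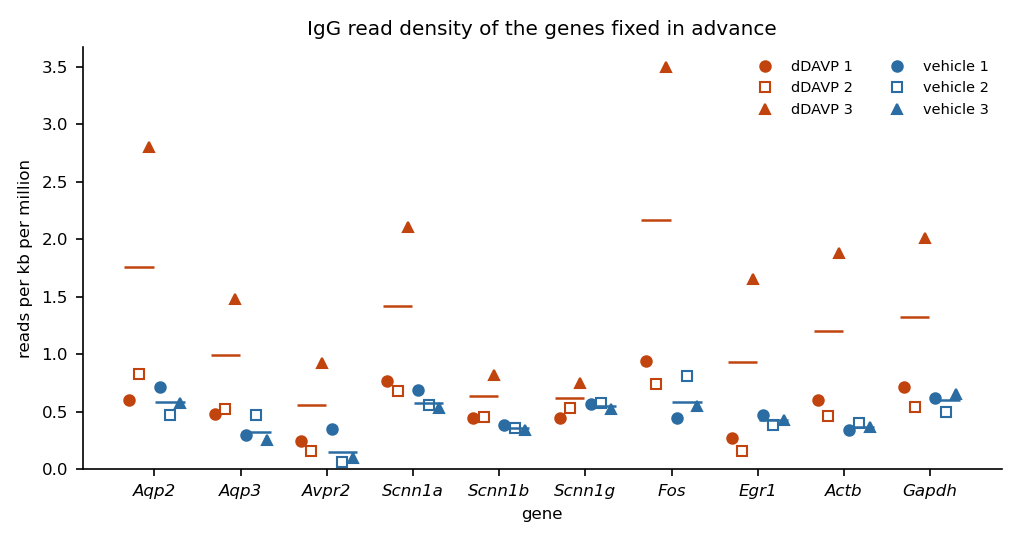
Read density (RPKM) of 10 genes fixed beforehand, with each of the 6 IgG libraries as a point and a bar at the mean of each group (n = 2, experiments 1 and 2 averaged). Over Aqp2 the dDAVP mean is 1.76 and the vehicle mean 0.584, with dDAVP experiment 3 at 2.80.

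Across the genome, edgeR's quasi-likelihood test called 0 of 30912 intervals, with 236 at an unadjusted p under 0.05 where chance gives 1545.6. DESeq2 also called 0, with 1117 at an unadjusted p under 0.05. The 236 intervals belonged to 172 genes, and all 236 were higher with dDAVP, a direction that was mixed without dDAVP experiment 3 (459 higher and 213 lower) and with a GC model as offset (190 of 446 lower). With experiment number as a block, the intervals under that unadjusted p were mostly lower instead (22 higher and 188 lower). The 236 intervals had a median GC content of 56.2% and a median length of 7.13 kb, against 45.3% and 18.2 kb over all intervals tested. Among the higher genes with the smallest p-values were Sap25, Hdgfl1, Rn4.5s and the homeobox gene Gsc. Their log2 ratios were 3.24, 2.30, 3.59 and 2.64. Sap25 had 72 reads with dDAVP against 8, and Rn4.5s, of 0.174 kb, had 47 against 4. The smallest among lower genes belonged to the odorant receptor gene Olfr566, the intestinal fatty acid-binding protein gene Fabp2, the taste receptor gene Tas2r129, the prolactin family gene Prl7d1, and Tex16. Their log2 ratios were −3.03, −1.40, −2.08, −1.28 and −0.93. Each of these genes had an adjusted p of 0.619 in edgeR's test.

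Without dDAVP experiment 3 the log2 ratio was 0.22 for Aqp2, 0.59 for Aqp3, 0.27 for Scnn1a, 0.28 for Scnn1b, −0.21 for Scnn1g, 0.47 for Fos, −1.03 for Egr1, 0.48 for Actb and 0.0023 for Gapdh. It was 2.04 for Sap25, 1.43 for Hdgfl1, 2.35 for Rn4.5s, 1.52 for Gsc, −2.29 for Olfr566, −0.92 for Fabp2, −1.53 for Tas2r129, −0.83 for Prl7d1 and −0.72 for Tex16. In that fit edgeR called 0 intervals, with 672 at an unadjusted p under 0.05, while dDAVP experiment 3 alone against vehicle gave 23054 calls. With the GC offset the log2 ratios were −0.052 for Aqp2, −0.57 for Egr1 and −0.44 for Gapdh, and those of the other 6 fixed genes tested kept their sign. On simulated data of the same size, the test recovered 0% of 2-fold, 31.3% of 4-fold and 87.9% of 8-fold changes. These changes were placed only in intervals with enough expected reads, and counts were drawn independently per interval. The rates therefore do not cover intervals with few reads or the shared GC bias of dDAVP experiment 3.

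Among 10 gene lists fixed beforehand, 3 were higher with dDAVP than other genes by limma's camera with a preset correlation and 0 with an estimated correlation, where each of the 3 had an adjusted p of 0.590. Of 31 principal cell and collecting duct genes, such as Aqp2, Aqp3 and Krt7, 24 were higher, with a median log2 ratio of 0.56 (camera adjusted p = 0.0072). Of 30 cAMP and serum immediate early genes, such as Fos, Egr2 and Fosl1, 24 were higher, with a median of 0.72 (adjusted p = 0.0072). Of 71 cytosolic ribosomal protein genes, such as Rpl41 and Rps15, 53 were higher, with a median of 0.32 (adjusted p = 0.0258). Without dDAVP experiment 3, whose reads favoured GC-rich genes, the adjusted p was 0.152 for the principal cell list, 0.814 for the immediate early list and 0.291 for the ribosomal protein list, and with the GC offset it was 0.835 for each. The ribosomal protein list also missed the threshold without dDAVP experiment 2 (adjusted p = 0.0744) or vehicle experiment 1 (adjusted p = 0.0623). No member passed on its own: edgeR called 0 genes of any list, over all genes tested or adjusted over the list alone, with 1 ribosomal protein gene, Rps2 (log2 ratio 1.92), and 1 vasopressin list gene, Adcy6 (1.297), at an unadjusted p under 0.05. DESeq2 called 0 intervals.

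The other 7 lists did not pass. Vasopressin signalling and transport genes split 14 higher to 13 lower, with a median of 0.02 (adjusted p = 0.292). Intercalated cell genes split 13 to 5 with a median of 0.65 (adjusted p = 0.121), genes of other nephron segments 12 to 9 with 0.24 (adjusted p = 0.613), and housekeeping genes 30 to 16 with 0.27 (adjusted p = 0.121). Tissue genes of other organs split 34 to 17 with a median of 0.50 (adjusted p = 0.120). RNA polymerase II and general transcription genes split 21 to 26, and their median of −0.17 and mean of 0.02 differed in sign (adjusted p = 0.669). Structural and nuclear noncoding RNA genes split 3 to 9 with a median of −0.49 (adjusted p = 0.231).

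The position of each list within the background of a library was asked next, as the list's median density over that of the median gene, with its percentile among 10000 random lists matched on length. Cytosolic ribosomal protein genes lay low in each of the 6 libraries. Their ratio was 0.833 ± 0.196 (SD, n = 2) with dDAVP and 0.620 ± 0.060 (SD, n = 2) with vehicle, at percentiles of 0 to 0.50. Rpl41 and Rps15 were their densest members, at 2.47 ± 2.37 and 2.03 ± 1.46 times the median gene with dDAVP and 0.848 ± 0.189 and 1.03 ± 0.02 with vehicle (SD, n = 2). In dDAVP experiments 1, 2 and 3 Rpl41 stood at 0.718, 0.879 and 4.15 and Rps15 at 1.203, 0.790 and 3.06. The X-linked Rps4x was the lowest, at 0.260 ± 0.280 and 0.410 ± 0.123 (SD, n = 2), with 0.295, 0.621 and 0.0625 in the 3 dDAVP experiments, the last from 2 reads. No other list lay outside the central 95% of random lists in each library by this measure. RNA polymerase II genes did by the list's mean density, at percentiles of 0.03 to 1.96, and after the GC model, at 0.29 to 2.28. By the fraction of bases covered, genes of other organs did, at 98.5 to 99.9. Over all intervals of each gene, housekeeping genes did, at 0.13 to 2.16.

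Without dDAVP experiment 3, housekeeping genes and the immediate early genes also lay below the range in the other 5 libraries. After the GC model neither list did in each of these libraries, with percentiles up to 7.19 for housekeeping and 25.9 for immediate early genes. Housekeeping genes had a ratio of 0.742 ± 0.032 (SD, n = 2) with vehicle, from Eef2, a translation elongation factor, at 1.06 ± 0.27 to the X-linked Hprt at 0.332 ± 0.080. Immediate early genes had 0.701 ± 0.009 with vehicle and 1.08 ± 0.50 with dDAVP (SD, n = 2), with Fosl1 and Egr2 densest and Jun lowest at 0.327 ± 0.210 with vehicle. In dDAVP experiment 3 the immediate early list stood at the percentile 67.1 and in the other 5 libraries at 0.06 to 1.74. Principal cell genes had ratios of 1.05 ± 0.32 with dDAVP and 0.755 ± 0.042 with vehicle (SD, n = 2). Their densest members were the potassium channel subunit gene Kcne1, at 1.21 ± 0.04 with vehicle, and the keratin gene Krt7, at 1.07 ± 0.05. Vasopressin signalling genes had 0.941 ± 0.097 and 0.859 ± 0.002 (SD, n = 2), with the adenylyl cyclase gene Adcy3 and the CREB coactivator gene Crtc2 densest. By the mean of the 6 libraries, which ranks the members named here, Scnn1b was the lowest of either list among members passing the count filter, which Avpr2 did not, with 0.422 ± 0.001 with vehicle, although Aqp3 had 0.376 ± 0.091 there.

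Tissue genes of other organs, such as those of pancreas, testis and liver, lay above the median gene. They had ratios of 1.47 ± 0.51 with dDAVP and 1.11 ± 0.02 with vehicle (SD, n = 2), at percentiles of 94.1 to 99.9. Among them Ins1, an insulin gene, stood at 1.96 ± 0.18 with vehicle, the sperm protamine gene Prm2 at 1.22 ± 0.33 and the plasma carrier gene Ttr at 0.770 ± 0.115. Genes of other nephron segments had 1.31 ± 0.34 and 1.151 ± 0.004 (SD, n = 2), with Miox and the organic anion transporter gene Slc22a6 densest and the podocyte gene Synpo lowest. Their ratios in vehicle experiments 1, 2 and 3 were 1.21, 1.09 and 1.15, so the vehicle SD understates the spread over the libraries. Intercalated cell genes had 1.35 ± 0.38 and 1.095 ± 0.019 (SD, n = 2), with the proton pump subunit gene Atp6v1c2 and Insrr densest and Hmx2 lowest. RNA polymerase II and general transcription genes had 0.839 ± 0.066 and 0.872 ± 0.016 (SD, n = 2), with Nelfcd and Polr2g densest and the X-linked Med14 lowest. Noncoding RNA genes had 0.580 ± 0.254 and 0.667 ± 0.168 (SD, n = 2), with Meg3 and Miat densest and Xist, the X inactivation RNA, lowest. Without matching on length 0 lists lay outside the range in each library.

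**Figure D3:**
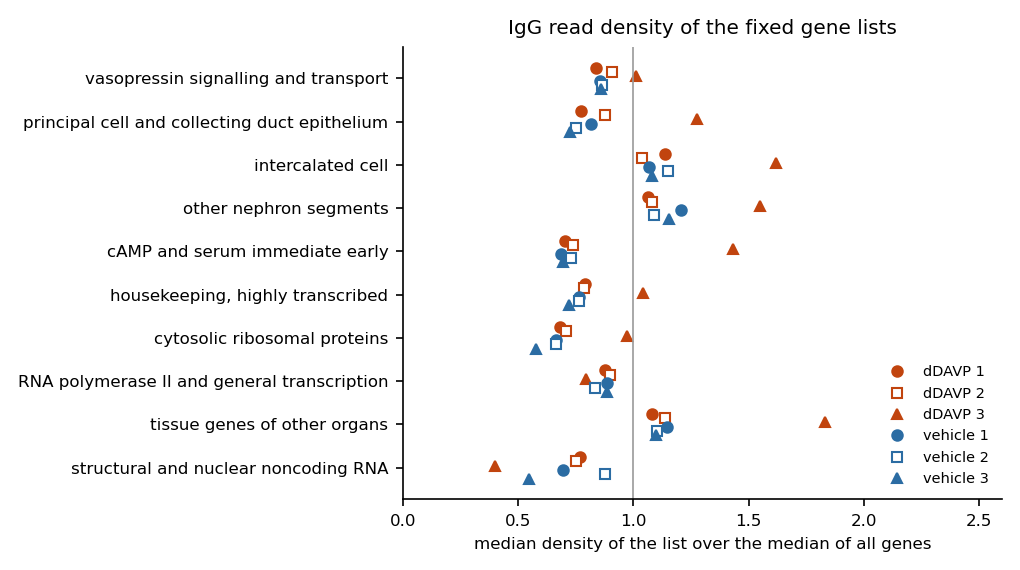
Median density of each of the 10 gene lists over the median of all genes, with each of the 6 IgG libraries as a point and a line at the median gene. Cytosolic ribosomal protein genes lie below the line in each library, and dDAVP experiment 3 has the highest ratio for 8 of the 10 lists.

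Background density by chromosome was compared with the median autosome. Chromosomes 12 and 19 stood at least 20% above it in each of the 6 libraries and chromosomes 4, 7, 18, X and Y at least 20% below, although chromosome 7 missed that margin by the median density of its intervals (0.808 in dDAVP experiment 3). Chromosome 12 had 1.79 ± 0.04 times the median autosome with dDAVP and 1.78 ± 0.04 with vehicle (SD, n = 2), and chromosome 19 had 1.41 ± 0.02 and 1.39 ± 0.03. Chromosome 4 had 0.667 ± 0.039 and 0.631 ± 0.007, chromosome 7 0.710 ± 0.089 and 0.619 ± 0.022, and chromosome 18 0.660 ± 0.007 and 0.674 ± 0.006 (SD, n = 2). The X chromosome had 0.285 ± 0.112 and 0.393 ± 0.028, and the Y chromosome 0.037 ± 0.002 and 0.036 ± 0.002 (SD, n = 2). The two-sided exact permutation test of dDAVP against vehicle cannot go below p = 0.333 at this size and so cannot pass the threshold (adjusted p at least 0.636 over 21 chromosomes). As a median over genes after the GC model, chromosomes 3, 10, 15 and 16 also stood above the margin, at 1.21 to 1.39 over the 6 libraries, and chromosome 12 was 1.37 to 1.43.

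**Figure D4:**
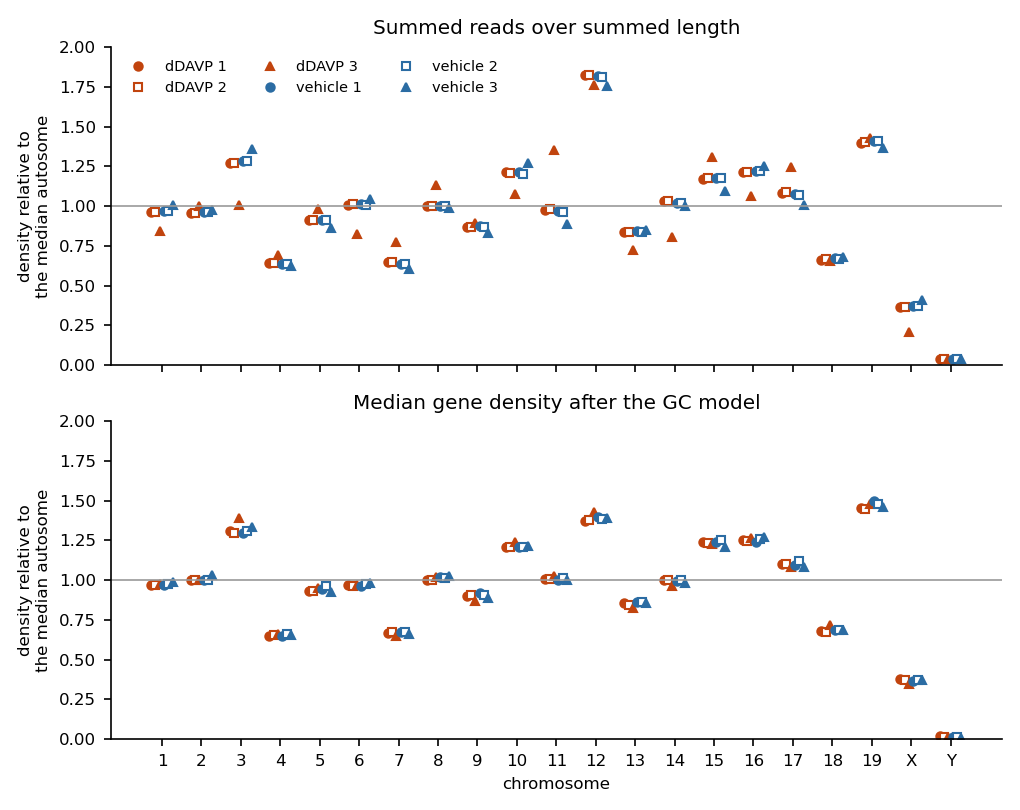
Read density of each chromosome over the median autosome, with each of the 6 IgG libraries as a point, from summed reads (upper panel) and as the median gene after the GC model (lower panel). In the upper panel chromosome 12 lies between 1.75 and 1.82 and the X chromosome between 0.206 and 0.412.

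The densest named genes clustered on chromosome 12. Of the 10 with the highest mean density, 6 lay there: Vash1, Angel1, Lrrc74a, Zdhhc22, Smoc1 and Cipc. Vash1, which encodes an angiogenesis inhibitor, lies at 86678700 to 86695681 and had 40.5 ± 20.6 times the median gene with dDAVP and 19.9 ± 4.9 with vehicle (SD, n = 2). dDAVP experiment 3 set that gap, at 55.1 against 25.6 and 26.3 in dDAVP experiments 1 and 2, and over the GC model Vash1 had 25.7 ± 3.5 and 25.3 ± 2.3 (SD, n = 2). Angel1, at 86700502 to 86726460, had 29.3 ± 4.5 and 24.0 ± 2.5, and Lrrc74a had 19.6 ± 2.7 and 15.9 ± 1.8. Smoc1, a matricellular protein gene at 81026808 to 81186414, had 13.8 ± 0.4 and 13.1 ± 1.1 (SD, n = 2). Zdhhc22, a palmitoyltransferase gene, had 19.4 ± 5.5 and 12.3 ± 3.1, and Cipc, a repressor of the circadian clock, 14.96 ± 3.24 and 11.8 ± 0.9. After the GC model these 6 genes stood between 10.8 and 28.4 times the model in each library.

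Outside chromosome 12, Chl1, a neural cell adhesion gene of 222 kb on chromosome 6, had 14.26 ± 14.97 times the median gene with dDAVP and 30.2 ± 6.3 with vehicle (SD, n = 2). dDAVP experiment 3 held its lowest value, 3.68, or 11.5 times the GC model, against 24.1 to 27.1 in the other 5 libraries. Duxf3, a double homeobox gene with tandem copies on chromosome 10, had 50.1 ± 40.5 and 14.8 ± 2.1, Sfi1 on chromosome 11 had 20.3 ± 1.1 and 18.5 ± 0.6, and the pseudogene Pisd-ps3, on an unplaced scaffold, had 39.9 ± 22.7 and 20.4 ± 4.4 (SD, n = 2). dDAVP experiment 3 set the gap of Duxf3 and Pisd-ps3, at 78.77 and 56.03, against 21.3 and 23.7 in dDAVP experiment 1. Over the GC model Duxf3 had 27.4 ± 1.5 and 28.5 ± 5.1 (SD, n = 2). Reads of Duxf3 and Pisd-ps3 cannot be assigned with certainty, since near copies exist. Outside the rule for named genes and chosen after its values were seen, the densest interval of at least 1 kb was the RefSeq record NR_046233 at 39842997 to 39848829 on chromosome 17, with no symbol in the tables used. It had 199.8 ± 162.1 times the median gene with dDAVP and 56.7 ± 13.6 with vehicle (SD, n = 2). dDAVP experiments 1 and 2 stood at 84.7 and 85.5 and experiment 3 at 314.4. Over the GC model the order turned, to 200.7 ± 63.8 with dDAVP and 254.1 ± 25.9 with vehicle (SD, n = 2). The interval has a GC content of 64.9%. For tiles of 65% GC or more the fitted weight was 1.36 in dDAVP experiment 3 and 0 in every other library. The turned order may therefore come from these weights. How much of the sequence of this record or of Sfi1 occurs once in the reference is not given here. Their reads may therefore come from more than 1 copy.

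**Figure D5:**
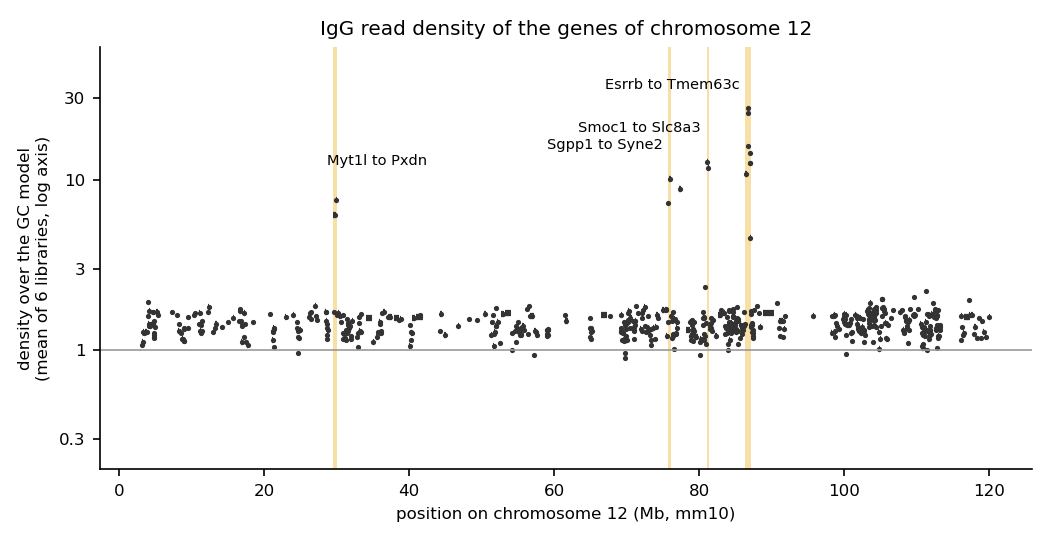
Read density of the 609 genes of chromosome 12 over the GC model (log axis), as the mean of the 6 IgG libraries, by position in Mb. Shading marks 4 stretches of dense genes, most genes lie near the median of 1.39, and Vash1 reaches 26.2.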

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

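The summing of experiments 1 and 2, which made the original 6 separate libraries an alternative, the GC model, leaving out experiments 1 and 2 of a group together, and experiments 1 and 2 alone were chosen after seeing the data. The cause of each difference was not tested except where named. The edgeR test called 0 intervals with other size factors, total counts, either other count filter, 1 interval per gene, autosomes only, the GC offset with or without the replicate block, or 6 separate libraries, with 131 to 1394 at an unadjusted p under 0.05. DESeq2, run on the summed samples, also called 0, with 1117. Total counts moved the median log2 ratio of all intervals to 0.24. The replicate block with a loess offset called 1 interval, Chl1, lower by a log2 ratio of −2.03. The GC offset without dDAVP experiment 3 called 3 intervals, 2 of 2700054A10Rik and 1 of Smo, each higher by 0.42. Experiments 1 and 2 alone as separate libraries gave 1321 calls, and 674 with the GC offset. In that fit the replicates are pairs that agree within sampling noise, so it compares libraries. Leaving out libraries gave 0 to 23054 calls, the latter with dDAVP experiment 3 alone against vehicle; a lone sample's spread was assumed like that of the other group.

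The replicate block gave 0 calls for intervals, with 210 at an unadjusted p under 0.05 (22 higher, 188 lower), and 3 gene lists. Deviations of same-numbered experiments correlated across genes at −0.23, −0.26 and −0.43. Since experiments 1 and 2 agree, these restate their contrast with 3 and cannot decide sample pairing. Of the gene lists, 0 passed with an estimated correlation, fry, or the GC offset (with or without the block, or without dDAVP experiment 3), and 1 with 6 separate libraries; leaving out libraries gave 0 to 3. Outside the range of random lists were 2 lists by the mean, by the covered fraction, over all intervals of each gene or after the GC model, 0 without matching on length, and 1 to 3 with libraries left out. By chromosome, 11 passed the margin after the GC model, 7 under each other summary (by median density with chromosome 10 in place of 7) and 7 to 10 with libraries left out.

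Log2 ratios of fixed genes turned sign as follows. With the GC offset, with that and the block, with that but without dDAVP experiment 3, and with it on 6 separate libraries, Aqp2 had −0.052, −0.067, −0.12 and −0.026, Egr1 −0.57, −0.70, −1.35 and −0.59, and Gapdh −0.44, −0.44, −0.31 and −0.36. Egr1 also had −1.03 without dDAVP experiment 3, −0.027 with 6 separate libraries and the block, and −0.98 and −1.15 with experiments 1 and 2 alone, without and with the GC offset. Scnn1g had 0.19 with total counts, 0.33 with the block and loess offset, and 0.055 without dDAVP experiments 1 and 2. With libraries left out, Scnn1g ran from −0.21 to 0.055 and Egr1 from −1.03 to 1.53. Over 19 named genes, 395 of 442 alternative log2 ratios kept direction and side of the threshold, 28 passed it and 19 turned sign. Densities of 39 genes moved by more than the spread in 2 of 350 values, and chromosomes in 17 of 84. The spread is the SD over the summed samples, dDAVP experiment 3 included. Leaving out a whole sample cannot move the mean by more than that spread, so the count for genes does not show stability. The promoter comparison was not run, and a pseudocount alternative has no meaning for counts. Depth limits genes such as Avpr2, with 1 to 18 reads per library.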

Other observations

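Each test below was chosen after the result it addresses had been seen, except the search for sequences found once in the numbered, X and Y chromosomes of the reference. Read density was high over 5 stretches of the genome in each of the 6 libraries. On chromosome 12, Myt1l, a neural zinc finger gene, and Pxdn, a peroxidasin, spanned 29528384 to 30017658 at 6.22 and 7.63 times the GC model as means of the 6 libraries. Sgpp1 and Syne2, a nuclear envelope protein gene, had 7.28 and 10.1 at 75714248 to 76110928. Smoc1 and the sodium-calcium exchanger gene Slc8a3 had 12.6 and 11.7 at 81026808 to 81333180. From 86361117 to 87090039, all 8 intervals screened were high (NR_033623 among them shares the reads of Cipc), from Tmem63c at 4.54 and the orphan nuclear receptor gene Esrrb at 10.8 to Vash1 at 26.2. The remaining stretch was Chl1 on chromosome 6, at 22.9. The stretches held 16 genes of 16748 screened, and 14 of the 25 genes at 3 times the median gene or more in each library lay on chromosome 12. C630031E19Rik, nested in Myt1l, had 1.66. On the same chromosome 594 of 609 genes were under 3 times the model. Outside the 5 stretches Fut8, a fucosyltransferase gene, had 8.86. The genes of this paragraph outside the rule for named genes were chosen after their values were seen.

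Several explanations for these stretches were weighed. For GC content, the median over the 16 genes was 12.1 times the GC model, so the fitted weights do not reach their density. The stretches were built from genes at 3 times the median gene in each library. A value well above the model was therefore nearly fixed in advance, and this test cannot decide on GC content. Reads shared with identical copies on the numbered, X and Y chromosomes of the reference are argued against. A median of 95.8% of their 32-base sequences occurred once there, against 94% over all genes screened, with Chl1 at 89%. Copies on scaffolds and near copies with mismatches were not searched. Extra DNA copies in the cell line stay open. The nearest genes outside the stretches had a median of 1.43 times the model, with 1.12 and 1.01 beside Chl1 on chromosome 6. The median of chromosome 12 was 1.39. Nearby genes at 3 times the median gene in each library were joined to a stretch, so low values beside it were nearly fixed in advance. They cannot decide the question, and no genomic DNA without precipitation was analysed here. No biological difference between groups was tested for this pattern, since both groups show it.

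The GC-rich profile of dDAVP experiment 3 was the next pattern. GC content bias may account for most of it. The model removed 85.5% of the variance across genes of this library's log2 ratio to the other 5. The SD of that ratio went from 1.27 to 0.48. Some removal was built in, since the weights were fitted to these same densities. Only 300-bp tiles were fitted, so the scale of the bias was not tested. A Pol II library in its place stays open. Highly transcribed housekeeping genes had a median log2 ratio to the other 5 of 0.29 before the model and −0.17 after it. The interval of the latter ran from −0.28 to 0.0035. The model was fitted to this same library and could remove any Pol II signal that follows GC content, so the test cannot decide. dDAVP itself is argued against as the source, because the other dDAVP replicate had a slope of log2 density of −0.10 per 10 GC points, against 1.82 here. What made the library prefer GC-rich fragments stays open.

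The likeness of experiments 1 and 2 within each group was the last pattern. A library given as 2 samples is a candidate explanation, since the larger ratio of chi-square to degrees of freedom was 1.02. Libraries made apart, each with its own duplicates, would give 1.72 for the vehicle pair from its estimated duplicate share, against 1.01 observed. That figure rests on an assumed distribution of copies per molecule, so the explanations cannot be told apart. No biological explanation was tested.

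With 6 separate libraries, 10 of the 10 splits into 3 and 3 gave 0 calls in edgeR, the real split included, and DESeq2 called 0 on the summed samples. The real split had 1201 intervals at an unadjusted p under 0.05 and the highest of the others 528. Only the split with 528 kept experiments 1 and 2 of each group together, as the real split does. The rest part libraries that agree within sampling noise, so they are not like the real split. The splits are too few for a share under 0.05.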
